A study of Mus musculus with 2 samples.

How the data were processed

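H3K9ac ChIP-seq libraries of 2 biological replicates were compared, each made from pooled stomachs of male and female B6NCrl mouse embryos at embryonic day 16.5. Per the labels, replicate 2 was a pool of 41 embryos. The labels give no such number for replicate 1. The replicates were assigned to their lists by the replicate number in the labels, and both belong to the same group, so no test between groups was made. Control libraries named in the labels were not analysed here.

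The authors deposited 4 peak lists in mm10, 1 for each replicate, 1 for the pooled alignments and 1 of replicated peaks. Per the file headers and the deposited descriptions of the files, the list of replicate 1 and the pooled list were derived from alignments and 2 further files that are not described, the list of replicate 2 from alignments and 1 further file, and the replicated list from the lists of both replicates and the pooled list. The replicates may therefore have been called against different controls. The aligner, the peak caller, its version, its threshold and the rule for a replicated peak are not given in the sources used here. The deposited signal value of a region is the authors' own enrichment value, whose scale is not stated. It served to rank and describe regions, and a mean ± SD over replicates assumes that the 2 lists share a scale. The deposited −log10 p and −log10 q of each region are also the authors' values, and the lowest −log10 p was just above 2 in every list, so many entries are weak. The deposited score is a display value derived by the authors and was not used in any result, and the deposited summit offset gave the position used to place a region in an exon, an intron or between genes and to find its nearest gene. All 47778 replicated entries on placed chromosomes were identical to an entry of the pooled list, which means that their signal values come from pooled reads. Read counts were not part of the lists, so the depth is unknown and intervals for single regions cannot be given.

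Regions on chromosomes 1 to 19, X and Y were kept, which left out 6 entries of the replicated list. Entries did not overlap within any list, so joining overlapping entries changed no number. Start sites came from GENCODE M21, and 1338 of 1338 single-exon transcripts had the same sequence in that annotation and in the genome used. A protein-coding gene was marked when a replicated region overlapped the 1000 bp either side of any of its start sites. Its signal value in a replicate was the largest among that replicate's regions in the window, and genes with a value in both replicates are given as mean ± SD (n = 2). Across these genes replicate 2 lay above replicate 1 by a median of 0.30 on the log2 scale. Each SD includes that general offset, so neither a large nor a small SD measures the agreement at a single gene. Where a region reached the start site of another protein-coding gene, as for 2934 marked genes, the value belongs to both. Domains were regions of the replicated list joined when at most 1000 bp apart. Random placements were made 100 times within chromosomes with bedtools 2.31.1, avoiding assembly gaps of at least 1000 bp.

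A set of 31 gene lists, the tests, the alternatives and the rule for named genes were written before the data were examined. The entry Ahsp of the erythroid list was not matched to an annotated gene, and 8 genes belong to more than 1 list (Bmp4, Gli1, Gli2, Gli3, Isl1, Rpl13a, Sfrp1 and Wnt5a). Marked members were compared with marked genes among all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. The test treats genes as independent, which neighbouring and co-regulated genes are not, so its p-values describe these 2 libraries. As an alternative, 10000 random lists were drawn within deciles of the observed-to-expected CpG ratio in the 500 bp either side of the start site, with a two-sided permutation p adjusted over the lists. After the data had been seen, the adjusted p that a list with all or no members marked would get was computed from hypergeometric probabilities, to find the lists for which no outcome could pass. Median signal value, median replicate difference and median domain width of a list are given as percentiles among 10000 random lists of the same size, which were also matched on deciles of mean signal for the replicate difference. Random lists from pools of at least 50 genes were drawn with replacement. Lists with fewer than 3 values were left out of these. Replicate differences are log2 ratios of replicate 2 to replicate 1, centred on the median of all genes with both values.

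Values are named for the 2 to 4 strongest members of each list and for all members on the marked or unmarked side where these were 5 or fewer, for the 10 strongest genes, for the 10 genes with the widest domains, for the 5 strongest and 5 widest distal regions, and for the 5 genes with the largest replicate difference in each direction among those with signal above the median. Other members are named only as marked or unmarked.

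The scripts were tested on simulated data. Regions kept in place were recovered as overlapping in 100% of cases, and moved regions overlapped by chance in 1.59%. Of simulated lists of 16 genes, Fisher's exact test called 100% with a true share of 100%, 23.0% with a true share of 90%, 69.5% with a true share of 30% and 1.00% with a true share of 67%. The percentile method placed 98.0% of lists shifted by 1 on the log2 scale outside the range for strength and 74.0% of lists shifted by 0.2 for the replicate difference, against 4.00% and 6.00% of lists without a shift. A list of 16 that is moderately above or below the other genes can thus be missed.

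The alternatives were a stricter threshold (−log10 q of at least 5), overlap rules of 50%, the strongest 20000 entries, −log10 p in place of the signal value, windows of 500 and 2500 bp, the outermost start site of each gene, each replicate's own list, the pooled list, matching on CpG content, and joining distances of 0 and 3000 bp. A pair of further alternatives was chosen after the data had been seen, namely only regions overlapped by both replicates, and only genes with no start site of another protein-coding gene within 3000 bp. Domain width was also compared among the 11518 marked genes whose domain came within 1 kb of no start site of another protein-coding gene, likewise chosen after the data had been seen. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.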

Results

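Acetylation of lysine 9 on histone H3 (H3K9ac), a chromatin mark found at active promoters, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in the stomach of mouse embryos at embryonic day 16.5. The animals were of strain B6NCrl, and each library was made from stomachs pooled over male and female embryos. There were 2 biological replicates of this single group and no other tissue, age or treatment, so the comparisons available are between the replicates and between the marked regions and the annotated genome. The label of replicate 2 gives a pool of 41 embryos. The deposited lists held 74564 enriched regions for replicate 1, 71634 for replicate 2, 83879 for the pooled reads and 47784 in a list that the authors named replicated peaks. No read counts were given with the lists, so the sequencing depth behind each region is unknown, and a gene without a region is not shown to lack the mark. Below, a protein-coding gene is called marked when a replicated region lay within 1 kb of any of its annotated start sites (genome build mm10), and its signal value is the authors' enrichment value of the strongest region there, given as the mean of the 2 replicate lists. Of 21938 protein-coding genes, 14625 (66.7%) were marked. Of the 14485 genes with a region in both replicates' own lists, 14393 were marked.

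The transcription factor genes of the gastric epithelium were all marked. These 16 genes include Sox2 and Gata4, which pattern the stomach, and the foregut factors Foxa1, Foxa2 and Foxa3. The highest signal values of the list belonged to Foxa3 (24.3 ± 4.16, SD, n = 2), Klf4 (20.7 ± 2.83), Grhl2 (18.7 ± 2.34) and Klf5 (16.2 ± 2.95). The region at Klf4, a regulator of epithelial differentiation, spanned positions 55528990 to 55532510 of chromosome 4, and that at Klf5 spanned 99298601 to 99302677 of chromosome 14. The region at Foxa3 also reached a start site of the neighbouring gene Sympk, so its value cannot be assigned to Foxa3 alone. All 16 genes of epithelial structure were marked as well, led by the adhesion genes Cdh1 (16.3 ± 5.11) and Epcam (13.2 ± 3.97) and the tight-junction genes Cldn7 (12.5 ± 2.48) and Ocln (12.2 ± 1.36). Both lists stood above other protein-coding genes (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over 31 lists, adjusted p = 0.0051 for each; the 95% exact confidence interval of 16 of 16 is 79.4 to 100%). In the list of replicate 1, 15 of the 16 transcription factor genes had a region, and they still stood above other genes (Fisher's exact test, adjusted p = 0.0433). Against random lists matched on the CpG content of the start site both calls ended in a two-sided permutation test. The adjusted p was 0.0796 for the transcription factors and 0.0688 for epithelial structure. A complete list is the highest possible outcome, so with these backgrounds of 82.6% and 80.2% neither list could have passed that test.

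By contrast, few genes for the secreted products and pumps of the mature gastric gland were marked. Only 3 of 15 had a replicated region, namely the proton pump subunit gene Atp4a (4.91 ± 0.614, n = 2), the trefoil factor gene Tff1 (3.45 ± 0.847) and Gkn3, which had a region in replicate 2 alone (signal value 3.25). The unmarked members included Atp4b, the intrinsic factor gene Gif, the pepsinogen gene Pgc, and the mucin genes Muc5ac and Muc6. This list lay below other genes (Fisher's exact test, adjusted p = 0.0022), but the share of 20.0% was close to the 21.9% of random lists of like CpG content (adjusted p = 1), against which even 0 marked genes would not have passed. Enteroendocrine genes were marked in 6 of 16 cases (Fisher's exact test, adjusted p = 0.0284), among them the transcription factor genes Isl1 (13.2 ± 2.44) and Rfx6 (5.21 ± 2.70), while the hormone genes Gast, Sst and Ghrl were not. That list remained below random lists of like CpG content, where 71.0% would be marked (permutation test, adjusted p = 0.000886, which rests on the smallest p that 10000 random lists can give). Its call by Fisher's exact test ended with the pooled list (adjusted p = 0.0866) and among genes without a start site of another gene within 3 kb (adjusted p = 0.223), a setting chosen after the data had been seen. The genes of the squamous epithelium that lines the forestomach were marked in 12 of 18 cases, led by Perp (17.0 ± 3.20), the desmoplakin gene Dsp (12.4 ± 0.280) and the basal keratin gene Krt15 (6.37 ± 1.83). The cornification genes Lor, Ivl, Sprr1a and Sprr3 and the keratin genes Krt14 and Krt6a had no replicated region. This share did not differ from other genes by Fisher's exact test (adjusted p = 1), but it lay above the 42.3% of random lists of like CpG content (adjusted p = 0.0434).

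Every listed gene of the gut mesenchyme was marked (20 of 20). The strongest were Meis1 (31.5 ± 3.50, n = 2), Nr2f2 (28.2 ± 4.92), Nr2f1 (24.0 ± 3.74) and Meis2 (23.8 ± 3.94), which all encode transcription factors, and the list also holds Barx1, a regulator of stomach mesenchyme, and Foxf1. All 18 smooth muscle genes were marked, led by the serum response factor gene Srf (33.7 ± 6.86), the tropomyosin genes Tpm1 (22.3 ± 1.73) and Tpm2 (14.2 ± 6.27), and the smoothelin gene Smtn (17.5 ± 4.44). The extracellular matrix list was likewise complete at 18 of 18, with Fbn2 (20.9 ± 2.24), Col5a1 (17.7 ± 4.03), Sparc (17.5 ± 2.46) and Col6a2 (17.4 ± 1.12) at its top. Each of the 3 lists lay above other genes (Fisher's exact test, adjusted p = 0.0028 for each). Random lists of like CpG content were marked at 69.4% for smooth muscle and 54.7% for the matrix genes (permutation test, adjusted p = 0.000886 for each), but at 93.5% for the mesenchyme list (adjusted p = 0.755). Of such random lists 23.1% were complete, so that test could not have passed for the mesenchyme list. The excess of that list was 33.4 percentage points over other genes but 6.47 over these random lists.

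Components of the hedgehog, Notch, BMP and Wnt signalling pathways were nearly all marked. In the hedgehog pathway all 15 genes were marked, with the receptor genes Ptch1 (31.0 ± 6.74, n = 2) and Smo (29.8 ± 5.08) strongest. All 15 Notch pathway genes were marked, led by Maml1 (28.4 ± 5.79) and Notch4 (26.6 ± 5.06), as were all 18 BMP pathway genes, led by the receptor gene Bmpr1a (30.6 ± 2.16) and Smad5 (29.4 ± 5.40). In the Wnt pathway 19 of 20 genes were marked, with Tcf7l2 (28.0 ± 1.33) and the receptor gene Fzd1 (23.5 ± 4.57) strongest; the exception was the inhibitor gene Dkk1, which had a weak region in replicate 1 alone (signal value 2.54). The cell cycle list was complete (15 of 15), with Cdk1 (22.7 ± 4.50) and Mcm4 (19.7 ± 2.22) on top, although the region of Mcm4 is shared with the start site of Prkdc. So were the housekeeping list (16 of 16) and the ribosomal protein genes (76 of 76), whose strongest members were Ubc (35.0 ± 1.81, region shared with Gm10382) and Rps6 (34.8 ± 2.73). All of these 7 lists passed Fisher's exact test, with adjusted p = 0.0074 for the hedgehog, Notch and cell cycle lists, adjusted p = 0.0028 for BMP, 0.0121 for Wnt, 0.0051 for housekeeping and 8.96e-13 for ribosomal proteins. None of the 7 passed the permutation test against random lists of like CpG content, with adjusted p = 0.522 for ribosomal proteins, 0.548 for BMP, 0.998 for hedgehog and Wnt, and 1 for Notch, cell cycle and housekeeping. No outcome above expectation could have passed there, since between 9.89% (Wnt) and 59.3% (cell cycle) of such random lists were complete.

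Genes of the other cell types in the organ were marked to varying degrees, mostly with weaker regions. Of 18 genes of enteric neurons and glia, the nerve cells of the gut wall and their supporting cells, 14 were marked, with Hand2 (16.7 ± 3.01, n = 2), Erbb3 (13.2 ± 1.31) and Elavl4 (10.3 ± 0.971) strongest. Plp1 and Nos1 had no region in either replicate, Phox2b had a region in replicate 1 alone (3.29) and Foxd3 in replicate 2 alone (3.76). Endothelial genes were marked in 14 of 16 cases, led by Fli1 (15.3 ± 0.740), Egfl7 (13.4 ± 3.18, a region shared with the start site of Gm20532) and Eng (12.3 ± 3.05), and Tie1 and Emcn were not marked. Neither share differed from other genes by Fisher's exact test (adjusted p = 0.541 for the enteric list and 0.141 for endothelium), but the endothelial share of 87.5% lay above the 61.7% of random lists of like CpG content (adjusted p = 0.0434). Mesothelial genes were marked in 7 of 9 cases (Fisher's exact test, adjusted p = 0.751), led by Aldh1a2 (8.40 ± 2.78) and Tbx18 (7.91 ± 2.63), with Upk3b and Gpm6a unmarked.

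Blood cell genes were marked less often than other genes. Among leukocyte genes 3 of 15 were marked, namely Coro1a (6.29 ± 0.449, n = 2), Spi1 (3.64 ± 0.853) and Laptm5, the last with a region in replicate 2 alone (4.46). In the replicates' own lists 4 of the 15 genes had a region in both, so some of these were not marked. Erythroid genes were marked in 5 of 14 cases, with Klf1 (18.7 ± 4.89), Nfe2 (9.88 ± 0.0925), Gypa (8.61 ± 0.936), Epor (6.96 ± 0.354) and Tal1 (6.87 ± 0.482). The globin genes Hba-a1, Hba-a2, Hbb-bt and Hbb-bs had no replicated region, which is uncertain because reads from near-identical copies can be lost in alignment. Both lists fell under other genes (Fisher's exact test, adjusted p = 0.0022 for leukocytes and 0.0307 for erythroid cells), and neither call held against lists of like CpG content (adjusted p = 1 for each), where even 0 marked leukocyte genes would not have passed. The leukocyte call by Fisher's exact test also ended in the list of replicate 2, where 7 of 15 genes were marked (adjusted p = 0.129), and with the pooled list (adjusted p = 0.115). The erythroid call by Fisher's exact test ended at the stricter threshold of −log10 q of at least 5 (adjusted p = 0.0583), with the outermost start site of each gene (adjusted p = 0.0693) and among genes without a close neighbour (adjusted p = 0.0782).

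Marker genes of other organs were included as a background. The lists for liver (4 of 15), lung epithelium (4 of 12), kidney (3 of 10), skeletal muscle (4 of 15), germ line (3 of 14) and olfactory receptors (2 of 1093) lay below other genes, with adjusted p = 0.0051 by Fisher's exact test for liver and for skeletal muscle, 0.0372 for lung, 0.0304 for kidney and 0.0028 for germ line, and a value too small to be represented for the olfactory receptors. Against lists of like CpG content the germ line and olfactory calls held (permutation test, adjusted p = 0.000886 for each), while those for liver (adjusted p = 0.998), lung (0.409), kidney (0.0688) and skeletal muscle (0.315) ended. The kidney call by Fisher's exact test also ended with either other window, with the outermost start site, with the list of replicate 1 (adjusted p = 0.123), with the pooled list and among genes without a close neighbour, and the lung call with the 2500 bp window (adjusted p = 0.0955) and the pooled list (adjusted p = 0.0883). The marked members in liver were the transcription factor gene Hhex (12.4 ± 2.10, n = 2), Trf (4.95 ± 1.53, shared with Gm20425), Apoa1 (3.18 ± 0.552) and Ttr, which had a region in replicate 2 alone (4.44). In lung they were Foxj1 (9.68 ± 1.39), Hopx (9.12 ± 0.673), Aqp5 (4.38 ± 0.0115) and Sftpc, whose region, called within 1 kb in replicate 2 alone, also reaches a start site of Bmp1. Kidney had Pax8 (4.21 ± 1.53), Lhx1 (3.75 ± 0.241) and Nphs1, which had a region in replicate 1 alone, shared with Kirrel2. Of the skeletal muscle genes, Mylpf (16.2 ± 7.39), Ckm (9.69 ± 2.63) and Tnni2 (8.19 ± 1.19) shared their region with the start sites of Tbc1d10b, Klc3 and Syt8, and Tnnt3 (3.12 ± 0.184) did not. The myogenic factor genes Myod1, Myf5 and Myog were unmarked. In the germ line list Gdf9 (20.0 ± 6.34) shared its region with Uqcrq, and Dazl (13.1 ± 2.79) and Tdrd1 (3.83 ± 0.337) had their own. The 2 marked olfactory receptor genes were Olfr94 (4.55 ± 0.265) and Olfr56 (3.34 ± 0.133), the latter sharing its region with Ifi47.

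The lists for pancreas, intestine, heart muscle and brain did not pass the test with the replicated list. Pancreas genes were marked in 9 of 15 cases, led by Nr5a2 (8.71 ± 0.622, n = 2), Nkx6-1 (7.62 ± 1.80) and Mafa (5.57 ± 1.35), with the hormone genes Ins1, Ins2 and Gcg unmarked (Fisher's exact test, adjusted p = 0.632). Intestinal epithelial genes were marked in 6 of 15 cases (Fisher's exact test, adjusted p = 0.0676). Their strongest member Mttp (20.1 ± 3.62) shared its region with Trmt10a, and it was followed by Vil1, Hnf4g (4.66 ± 0.822) and the caudal-type homeobox gene Cdx1 (4.41 ± 0.501). In the list of replicate 2 this list lay below other genes by Fisher's exact test (adjusted p = 0.0375), while in that of replicate 1, with 9 of 15 genes marked, the adjusted p was 0.658. Heart muscle genes were marked in 9 of 15 cases (Fisher's exact test, adjusted p = 0.632), with Myl4 (28.5 ± 0.0758, region shared with Cdc27) and Ryr2 (8.78 ± 1.62) strongest, and at the stricter threshold this list lay below other genes (adjusted p = 0.0227). Brain genes were marked in 8 of 17 cases, led by Satb2 (13.7 ± 2.30), while the forebrain factor gene Foxg1 and the GABA synthesis genes Gad1 and Gad2 had weak regions in replicate 1 alone. The brain share of 47.1% did not differ from all other genes (Fisher's exact test, adjusted p = 0.148), but it lay below the 88.1% of lists of like CpG content (adjusted p = 0.000886) and below other genes at the stricter threshold (adjusted p = 0.0269). In the list of replicate 1, 11 brain genes were marked and the difference shrank from -19.6 to -2.94 percentage points (Fisher's exact test, adjusted p = 0.799).

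**Figure D1:**
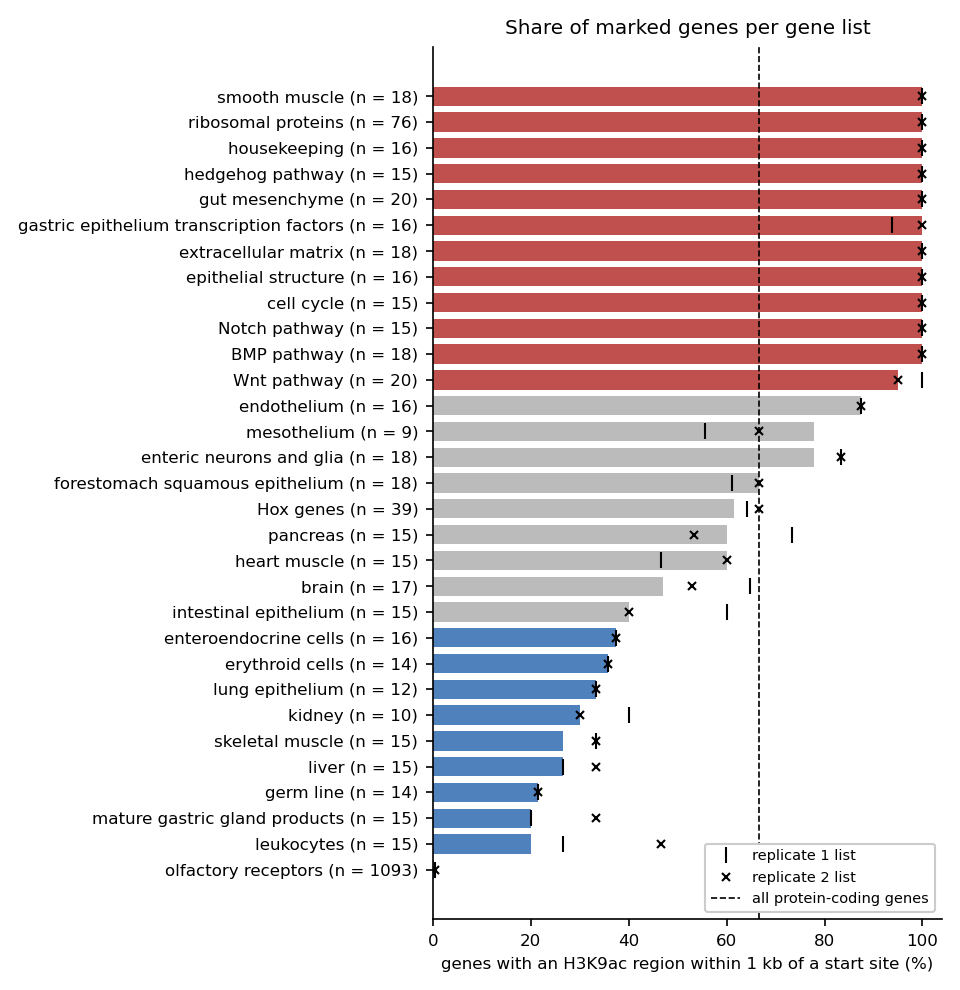
Share of genes marked in the replicated list (bars, %) for each of 31 gene lists, with the share in each replicate's own list (vertical ticks for replicate 1, crosses for replicate 2); red and blue bars are lists above and below other genes by Fisher's exact test at an adjusted p of 0.05, grey bars did not pass, and the dashed line is the 66.7% of all protein-coding genes. In 11 of the 12 red lists every gene was marked, and olfactory receptors, lowest of the 10 blue lists, had 0.183%.

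The Hox genes, whose expression along the body axis follows their order in the 4 clusters, divided by paralogue number. All 23 genes of paralogue groups 1 to 8 were marked, against 1 of 16 in groups 9 to 13. The marked gene of the second set was Hoxb9, with a weak region (3.96 ± 0.607, n = 2) at 96271638 to 96271864 of chromosome 11. The strongest Hox start sites were those of Hoxa4 (23.9 ± 3.49, at 52189830 to 52191773 of chromosome 6), Hoxc4 (19.9 ± 9.96), Hoxa5 (19.6 ± 4.70) and Hoxa2 (18.7 ± 7.07). In the HoxD cluster Hoxd1 was at 3.51 ± 0.0787 and Hoxd8 at 8.06 ± 3.21, and Hoxd3 and Hoxd4 shared a region (4.58 ± 0.734). In the replicates' own lists, 22 and 23 genes of groups 1 to 8 and 3 genes of groups 9 to 13 in each were marked; Hoxb1 lacked a region in replicate 1. Taken as a list of 39 genes the family did not differ from other genes (24 marked, Fisher's exact test, adjusted p = 0.574), but it lay below lists of like CpG content, in which 91.0% of genes were marked (permutation test, adjusted p = 0.000886).

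**Figure D2:**
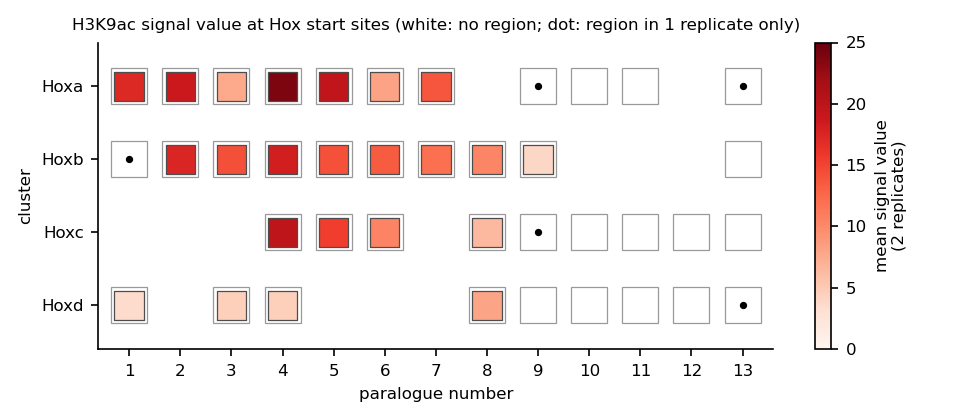
Mean signal value of the 2 replicates (colour) at the start site of each Hox gene, by cluster (rows) and paralogue number (columns); an empty square had no region in either replicate, a dot marks a region in only 1 replicate, and a place without a square has no gene. Coloured squares fill paralogues 1 to 8 except Hoxb1 (region in replicate 2 alone), and Hoxb9 at 3.96 is the only coloured square beyond them.

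Acetylated domains were formed by joining regions at most 1 kb apart, and their width was compared between gene lists. The widest domain of the genome, 47898 bp at 96298774 to 96346671 of chromosome 11, covered the start sites of Hoxb3, Hoxb4, Hoxb5 and Hoxb6. It was followed by a 24121 bp domain at Hoxa1, Hoxa2 and 5730596B20Rik (chromosome 6, 52157525 to 52181645), a 23611 bp domain at Midn and Cirbp (chromosome 10, 80145669 to 80169279) and a 21647 bp domain at Foxf1 (chromosome 8, 121071193 to 121092839), a transcription factor gene of the gut mesenchyme. Over all marked genes the median domain width was 1973 bp. It was 8513 bp for marked Hox genes, 8016 bp for the gut mesenchyme list, 5200 bp for gastric epithelial transcription factors, 4721 bp for smooth muscle and 4635 bp for the Notch pathway. A domain shared by several genes was counted once for each of them, as the widest one was for Hoxb3, Hoxb4, Hoxb5 and Hoxb6. The Hox median and its percentile therefore rest on fewer domains than genes. Of the 24 marked Hox genes, 10 had a domain that reached no other protein-coding gene, with a median of 1180 bp (percentile 2.28 among random lists of such genes), a setting chosen after the data had been seen. In all, the medians of 13 lists lay in the highest 2.5% of 10000 random lists of marked genes of the same size. The other 8 were BMP (3720 bp), hedgehog (3597 bp), Wnt (3594 bp), housekeeping (3432 bp), epithelial structure (3200 bp), cell cycle (3136 bp), extracellular matrix (2932 bp) and ribosomal proteins (2756.5 bp). With regions left unjoined, smooth muscle moved to percentile 92.7 and cell cycle to 62.2, inside the range, and cell cycle was at 97.1 with joining up to 3 kb. In the lowest 2.5% lay 7 lists. Mature gastric products (400 bp), kidney (700 bp) and germ line (791 bp) had only 3 genes each. The others were enteroendocrine cells (841.5 bp, 6 genes), heart muscle (1056 bp, 9 genes), enteric neurons and glia (1163.5 bp, 14 genes) and brain (1207 bp, 8 genes). Random lists of like signal value were not drawn for these lists, so narrow width was not separated from weak signal. Of the 7 narrow lists, 5 left the lowest 2.5% in at least 1 other setting. With regions left unjoined, germ line was at percentile 4.62, enteric neurons and glia at 4.91 and kidney at 3.39. Joining up to 3 kb put brain at 40.3. Germ line was at 5.12 in the list of replicate 2 and 3.54 in that of replicate 1, where heart muscle was at 2.86. These percentiles describe 2 libraries, and genes are not independent replicates.

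The median signal value at start sites was 22.6 for housekeeping genes and 21.8 for ribosomal protein genes, above 99.99% and 100% of random lists, against 15.2 over the 14485 genes marked in both replicates. The median was 12.2 for gastric epithelial transcription factors (percentile 11.3) and at percentile 16.2 for the gut mesenchyme list, which was at 41.5 in the list of replicate 2 and 33.1 in that of replicate 1. A total of 11 lists fell in the lowest 2.5%, among them leukocytes (3.38), brain (4.36), enteroendocrine cells (4.71), forestomach squamous epithelium (5.14), enteric neurons and glia (5.39), endothelium (5.73) and smooth muscle (10.2, percentile 1.67). The 10 strongest start sites of single genes belonged to Bicral (43.3 ± 7.38, n = 2), Srsf6 (35.5 in replicate 1 and 48.2 in replicate 2), Srsf4 (40.9 ± 4.03), Rbm39 (40.6 ± 3.20), Ep300 (39.0 ± 1.73), Wtap (38.9 ± 7.30), Hnrnpu (38.7 ± 7.09), Nrf1 (38.8 ± 9.57), Tnpo1 (38.0 ± 1.92) and Clk1 (38.3 ± 8.98). Srsf6, Srsf4, Rbm39, Hnrnpu and Clk1 encode RNA-binding splicing proteins or, for Clk1, a kinase of splicing factors, and Ep300 encodes a histone acetyltransferase. The means of these 10 genes lay within the SD of Bicral of each other. That SD includes the higher values of replicate 2 at most genes, and the order of the 10 was not tested. Across 14393 genes, domain width and signal value were correlated with a Spearman rho of 0.502, a description across genes, which are not independent replicates.

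**Figure D3:**
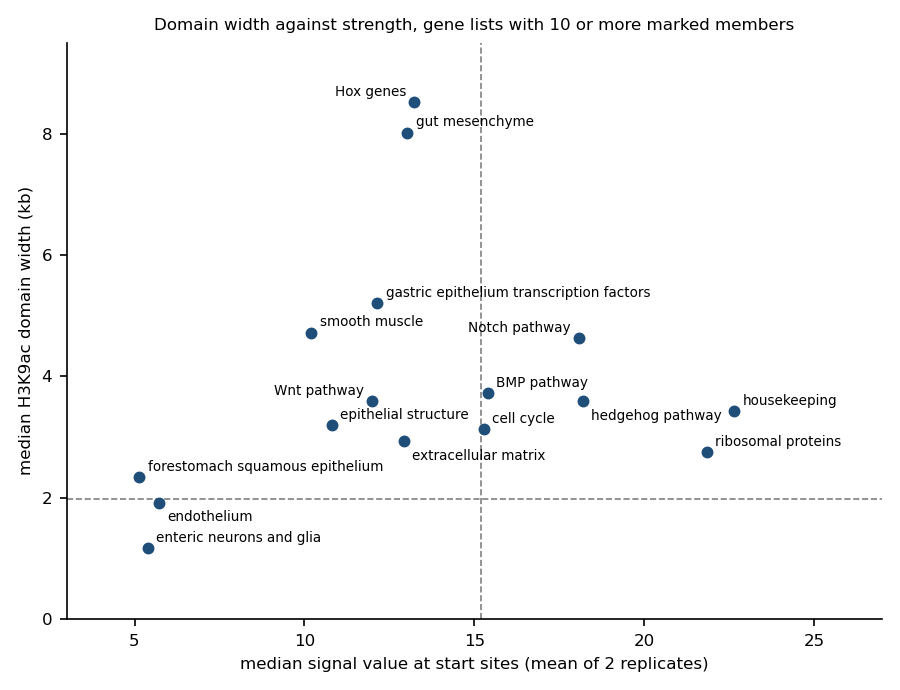
Median H3K9ac domain width (kb) against median signal value at start sites for gene lists with at least 10 members marked in both replicates; each point is a list and the dashed lines are the median width over all marked genes (1973 bp) and the median signal value over genes marked in both replicates (15.2). Hox genes and gut mesenchyme lie highest, and housekeeping and ribosomal protein genes lie farthest to the right.

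The replicates shared most of their strong regions and a minority of their weak ones. Of the regions of replicate 1, 60.3% overlapped a region of replicate 2 by at least 1 bp, and 61.2% of the regions of replicate 2 overlapped replicate 1. In 100 random placements within chromosomes these shares were at most 3.42% and 3.20%. When regions were ranked by signal value into 4 classes of equal size, 99.8% of the strongest class were shared in either replicate, while in the weakest class 32.2% were shared in replicate 1 and 34.2% in replicate 2. Requiring overlap of 50% of both regions lowered the shares to 42.0% and 43.7%. Across 39720 shared regions the log2 signal values had a Spearman rho of 0.858 and a Pearson r of 0.923, and across genes marked in both replicates rho was 0.901. Values at start sites in replicate 2 exceeded those in replicate 1 by a median of 0.30 on the log2 scale, with an SD of 0.34 across genes. With that median set to 0, the start sites lowest in replicate 2 were those of Zcchc8 (-1.24), Ccdc142 (-1.24, region shared with Mrpl53), Camk2d (-1.21), Snx13 (-1.10) and Tnnc1 (-1.09, region shared with Nisch). The highest were Cnot8 (1.40), Tgs1 and Tmem68, which share a region (1.16), Ccz1 (1.12) and Znrd1 (1.01, shared with Znrd1as). With 1 library per pool these differences have no test.

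**Figure D4:**
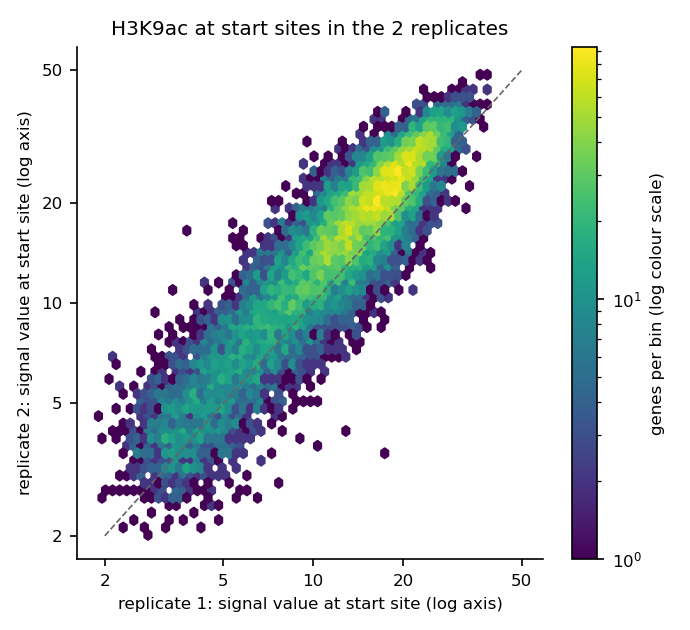
Signal value at the strongest region within 1 kb of a start site in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis) for 14485 genes marked in both replicates; colour gives the number of genes per bin and the dashed line marks equal values. The cloud follows the diagonal (Spearman rho 0.901) and lies above it at high values.

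Replicate differences were also compared by gene list. Among 28 lists with enough members, 3 had a median in the lowest 2.5% of random lists of like signal and none in the highest 2.5%. These 3 were ribosomal proteins (median -0.05, percentile 1.37), housekeeping genes (-0.13, percentile 1.69) and the 4 enteroendocrine genes marked in both replicates (-0.56, percentile 1.94). That median rests on few genes, of which Isl1 (-0.68), Nkx2-2 (-0.58) and Insm1 (-0.54) were lower and Rfx6 (0.81) was higher in replicate 2. With the same 3 lists in a 2500 bp window, the ribosomal and housekeeping lists moved to percentiles 2.58 and 2.68, inside the range, and with −log10 p in place of the signal value housekeeping moved to 13.7. The enteroendocrine list stayed outside in both settings, but it had too few genes for a value at −log10 q of at least 5. The Hox list moved from percentile 80.2 to 99.3 with the 2500 bp window.

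Start sites accounted for 24359 of 47778 replicated regions, against at most 9.04% in 100 random placements. These regions were wider than the others (median 968 bp against 402 bp) and stronger (median signal value 9.55 against 3.58), and they held 70.7% of the covered sequence. In the replicates' own lists, which hold more weak regions, 41.5% and 42.9% of regions lay at start sites. The share of marked protein-coding genes was higher at start sites of higher CpG content. In 4 classes of equal size it was 8.95% in the lowest, then 64.0%, 95.3% and 98.4%.

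The remaining 23419 regions (49.0%) lay more than 1 kb from any annotated start site, with 13255 in introns, 8037 between genes and 2127 in exons, at a median of 10488 bp from the nearest protein-coding start. The strongest of them lay between genes 5990 bp from Zfp869 (chromosome 8, 69716249 to 69716969, pooled signal value 34.9), in an exon 2323 bp from Zfp503 (chromosome 14, 21984393 to 21988436, 33.6), and between genes with Spag6 (chromosome 2, 18766351 to 18767700, 29.6), Cbx8 (chromosome 11, 119055711 to 119057674, 28.7) and Chd7 (chromosome 4, 8910779 to 8912162, 27.5) as nearest genes. The widest was a region of 4956 bp in an intron 7218 bp from a start site of Mylk, the smooth muscle myosin light chain kinase gene (chromosome 16, 34921448 to 34926403). It was followed by 4666 bp between genes near Hoxb4 (chromosome 11, 96308494 to 96313159) and by intronic regions nearest to Kdm6b (4342 bp), Thra (4300 bp) and Fam129b (4058 bp). Distal regions were called in both replicates less often than start-site regions (68.7% against 91.2%). Their number changed with the list and threshold, to 43635 and 40899 in the lists of replicates 1 and 2 and 11764 at the stricter threshold.

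The X chromosome carried fewer regions than any autosome. It had 5.24 replicated regions per Mb, against an autosomal median of 20.3 and an autosomal minimum of 12.8, a ratio to the median of 0.258. On the X, 47.2% of 948 protein-coding genes were marked, compared with 68.1% of autosomal genes and at least 55.2% on each autosome. Chromosome Y had 3 regions. These are values of a single group without a test.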

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

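A total of 6 regions of the replicated list lay on scaffolds that are not placed in the chromosome assemblies and entered none of the comparisons. They were flagged by a fixed rule for data outside the main measurement, since their number exceeds the 3 that a count of 0 allows. Reads can align to such scaffolds, so passing the rule shows no excess. The pooled list and the list of replicate 2 held 9 such entries each, and that of replicate 1 held 8. Of the 6 replicated regions, 4 lay on a scaffold assigned to chromosome X, with a highest pooled signal value of 11.4, 1 on a scaffold assigned to chromosome 4 with a signal value of 23.0, and 1 on an unassigned scaffold with a signal value of 2.41. No explanation was tested for them.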

How the results depend on the processing

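The settings with only regions called in both replicates and with only isolated genes were chosen after the data had been seen, the others before. Leaving entries unmerged gave identical values. A Jaccard index or correlation has no spread between replicates here, so fixed tolerances of 0.005 and 0.01 decided whether it had moved. No paired analysis was possible because there is a single group. All 12 lists above other genes stayed above in each of the 9 alternatives other than CpG matching, and of the 10 lists below, 6 to 10 stayed below in these. With random lists matched on CpG content, 4 lists lay above and 5 below, of which 2 and 3 had the same call as in the main comparison. Of the 10 calls above and 7 below that ended, 10 and 2 were of lists for which no outcome on that side could have passed. This was computed after the result was seen. Too many or too few genes of like CpG content were marked for lists of their size, so losing the call alone says nothing about stability there. In each of these lists the difference from the matched background was smaller than that from other genes. For all other changes the cause was not tested.

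With −log10 q of at least 5 the pooled list kept 34008 regions, replicate 2 28283 and replicate 1 26443, the shared percentages were 87.2 and 80.9, the Jaccard index 0.737 (main 0.566), Spearman's rho 0.902, Pearson's r 0.903, the share at start sites 64.2%, marked genes 64.7%, the ratio of X to autosomes 0.329 and the distal regions 11764. Shared percentages were 55.6 and 56.3 with overlap of 50% of the shorter region, 42.0 and 43.7 with 50% of both regions (rho 0.903), and 91.2 and 90.6 in the strongest 20000 entries (Jaccard index 0.776). With −log10 p, rho was 0.877 and r 0.934. Shares at start sites and of marked genes were 45.5% and 66.0% with 500 bp, 61.8% and 67.9% with 2500 bp, 40.7% and 63.1% with the outermost start site, 37.0% and 69.1% with the pooled list, and 58.0% and 65.5% with regions called in both replicates. With the pooled list 6 lists lay below other genes. With the 2500 bp window 1 list had a replicate difference above and 1 below the random range.

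Leaving out a replicate gave 41.5 to 42.9% at start sites, 67.6 to 68.0% marked genes and 40899 to 43635 distal regions. The X ratio was 0.195 in the list of replicate 1 and 0.220 in that of replicate 2.

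Directions turned only in lists that had not passed the test, apart from erythroid cells. In percentage points above other genes, the forestomach list (main 0.00152) gave -9.18 at the stricter threshold, -10.4 with 500 bp, -1.98 with the outermost start site, -2.42 with the pooled list, -9.95 with regions called in both replicates, and -6.54 to -1.32 without a replicate. Mesothelium gave -12.1 to -1.32 and pancreas -14.7 to 5.69 without a replicate. Hox genes gave 0.145 and heart muscle 10.9 with the pooled list, and Hox genes 0.832 among isolated genes. CpG matching gave -5.35 for enteric neurons and glia, 4.68 for erythroid cells, 3.41 for pancreas and 13.8 for heart muscle. Over all lists and alternatives, 255 results stayed on their side, 31 lost and 7 gained the call on the same side, and 17 turned direction, among them a further lost call, of erythroid cells with CpG matching. By domain width, smooth muscle and cell cycle left the highest 2.5%, and germ line, brain, enteric neurons and glia, kidney and heart muscle the lowest 2.5%, in at least 1 setting. Forestomach, intestine, leukocytes, liver, pancreas and skeletal muscle entered the lowest 2.5% in at least 1 setting. Of the list percentiles, 118 stayed within their spread, 164 moved and 0 called ones turned direction. For named genes 1921 values stayed within the SD of the replicates and 31 did not. The value of a single replicate always lies within that SD of the mean of 2. Values without a replicate could therefore not have moved, and their part of the count says nothing about stability. Depth is unknown, so weak regions and unmarked genes are the least certain results.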

Other observations

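Of the 8 tests below, 4 were chosen only after the result was seen, namely the test of domains that reached no other gene, both tests of the regions not called in both replicates and the chance test of the chromosome Y genes. The noncoding genes, the comparison of distal regions by list and the separate count of regions over 1 kb from those called in both replicates were also chosen after the data had been seen.

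The sixth widest domain held no protein-coding start site. It spanned 18919 bp of chromosome 18 (61648505 to 61667423) and held the start sites of Carmn, a long noncoding RNA gene known from smooth muscle, and of the microRNA gene Mir143. The signal value at Carmn was 13.9 ± 0.888 (SD, n = 2). The Foxf1 domain likewise held the start of the noncoding gene Fendrr (13.1 ± 1.26), and the HoxA domain that of Hotairm1 (17.3 ± 2.21), though values at such overlapping genes cannot be separated.

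Distal regions gathered near particular genes. The largest numbers of distal regions with a given nearest protein-coding gene were 86 for Gse1, 81 for Zmiz1, 59 for Zfp36l1 and 45 for Casz1. Sh3pxd2a, Tns1 and Zfhx3 followed with 41 each. Further down the ranking, Smad7, a feedback inhibitor of TGF-beta and BMP signalling, had 38, and the Notch target gene Hes1 had 32. Other genes not named here ranked between these. Among marked genes, the median number of such regions was 6.5 for the gut mesenchyme list, 4.5 for extracellular matrix, 4 for gastric epithelial transcription factors and 3 for smooth muscle, in each case at percentile 99.98 or higher among 10000 random lists of marked genes. Signalling and other epithelial lists were also high, with 3 for Wnt (percentile 99.98), hedgehog (99.96) and Notch (99.92), 2 for BMP (99.5) and forestomach (98.7), and 1.5 for epithelial structure (97.8). It was 0.5 for housekeeping genes (percentile 63.5), 0 for ribosomal proteins and 0 for Hox genes. The distance between neighbouring genes was not matched, and genes with more empty sequence around them collect more regions.

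Wide domains were the first pattern weighed. Random lists were matched on the CpG number within 2500 bp of the start site. Of the 13 lists with wide domains, 13 then stayed in the highest 2.5% (lowest for Wnt, percentile 97.9). With random lists matched on signal value, 13 also stayed. These results argue against the CpG number in that window or stronger regions as the whole cause. A CpG-rich stretch that runs beyond the window was not matched and stays open. The 12 lists other than Hox also stayed in the highest 2.5% among genes with no other protein-coding start site within 3 kb. They did so too among genes whose domain reached no other protein-coding gene (lowest percentile 99.7). For these 12 lists this argues against joined protein-coding neighbours. Noncoding start sites were not screened in either test. The domains of the mesenchyme genes Foxf1, Meis2 and Nr2f2 held some, so joining with noncoding neighbours stays open. For Hox the first of these tests decides nothing, as 11 of the 20 genes it kept shared a domain with another gene, and in the second Hox fell to percentile 2.28, but that test leaves out the widest domains of a dense cluster and Hox was at 99.98 with regions left unjoined, so joining stays open for it. With regions left unjoined 11 lists lay in the highest 2.5%, without smooth muscle and cell cycle, the number of start sites per gene was not matched, and no biological explanation was tested.

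A further pattern concerned 9490 replicated regions (19.9%) that were not overlapped by regions of both replicates, 742 of them by neither, with a median signal value of 3.17, against 5.47 for the others. Chance calls spread evenly along chromosomes would lie at start sites as often as random placements. Of the 9490 regions 22.6% did, against at most 8.08% at random, so evenly spread calls do not account for them as a set. Random placement does not copy the distribution of background reads, so background calls stay open. The regions may also be edges of stronger regions, as 37.9% lay within 1 kb of a region called in both replicates (4.55% on average at random). That leaves the edge explanation open for part of them. Among the 5889 farther away, 15.9% lay at start sites, against at most 6.26% of random placements as far away. These were selected not to be edges within 1 kb, so their share bears only on even placement. No biological explanation was tested.

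The last pattern was a lower signal at chromosome Y genes in replicate 2, where the centred log2 difference was -0.69 at Uty and -0.62 at Ddx3y. The median of -0.66 lay at percentile 2.74 of random gene pairs of like signal, so chance could account for it. Fewer male embryos in that pool is another candidate explanation, which would raise Xist, expressed from the inactive X of females. The difference at Xist was 0.031, within the SD of 0.40 of genes of like signal, and cannot decide. Chromosome X had more entries in the list of replicate 2 than in that of replicate 1 (1140 against 1046), while every autosome had fewer. The median centred difference at X genes was 0.004. These values were not tested, and the sex make-up of the pools stays open.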
